A study of Mus musculus with 15 samples.

How the data were processed

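RNA was sequenced from 15 mouse aorta libraries, 5 each from Sham, AngII and AngII + RvE1 mice. The deposited table holds gene symbols and 1 value per library, treated here as FPKM, that is, as scaled to gene length and library depth. The file names no unit. Values have decimals, and the 15 columns have unequal sums between 385846 and 514281. Low values are not whole multiples of a single read's worth, so they are not whole read counts or CPM of such counts. That check compared libraries within a gene, so it cannot show scaling to gene length, which was assumed. TPM over a wider set of genes cannot be excluded, and log2 differences would then carry a constant shift per library. The submitters' processing notes name the mm10 build. The aligner, the quantifier and the annotation version are not given in the sources used here. All 34714 symbols are in the RefSeq table of GRCm38.p6, which gave the coordinates.

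Genes with a value of at least 1 in at least 5 libraries were kept, 12603 in all, and values were transformed as log2(FPKM + 1). limma-trend (limma 3.58.1 in R 4.3.3) was fitted with 1 mean per group over all 15 libraries, and 3 contrasts were tested two-sided with empirical Bayes moderation and Benjamini-Hochberg adjustment over all genes of a contrast, at a threshold of 0.05. The plan was written for read counts, with this test as its stated fallback for normalised values, and the fallback was used because the file holds no counts. Because of the added 1, differences of genes with low values are pulled toward 0. The groups, contrasts, test, filter, gene lists, rule for naming genes and most alternatives were chosen before the data were examined. The rescaling, the smooth muscle and lymphocyte covariates, the omission of AngII libraries 3, 4 and 5, and the array weights were chosen after seeing the data.

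The rule names, for each comparison, the 8 largest rises and 8 largest falls among called genes with a mean of at least 5 in the higher group and no overlap between libraries, leaving out unnamed symbols and immunoglobulin or T cell receptor segments. It adds up to 4 called members of each list with the smallest adjusted p, a fixed set of genes of the angiotensin, resolvin, matrix and inflammation fields, and the 8 strongest opposite calls. Where fewer than 5 genes qualified, the 8 genes with the smallest p were taken. The text names some further list members and clock genes from the same tables. Some genes that the rule names are not reported here, though they count in every total of genes and list members.

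The 37 gene lists were tested with camera, at a preset correlation of 0.01 and with a correlation estimated per list, adjusted over 108 tests. List means per library were compared by exact two-sided permutation of the libraries, where 5 against 5 gives a smallest possible p of 0.00794. Because AngII enters both of the first comparisons, 100 sets without group effects were simulated by flipping the signs of residuals of whole libraries. An earlier scheme that exchanged residuals between libraries was replaced after its output was seen, since it ignored the larger spread of AngII libraries; the scheme used gives more opposite calls by chance. The AngII libraries were also divided between the comparisons in 20 ways. For each comparison 100 of the 126 ways of dividing 10 libraries in 5 and 5 were fitted again.

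The procedure was tested on simulated data with 200 changed genes among the 12603. At a log2 change of 1, 71%, 75% and 79% were recovered for AngII against Sham, AngII + RvE1 against AngII and AngII + RvE1 against Sham. At a change of 2 the shares were 96%, 98% and 96%. False calls numbered 8 of 175, 7 of 180 and 8 of 183. The simulated noise was drawn independently for each gene and library, with 1 SD per gene over all groups. It held none of the correlation between genes or the differences between libraries of the real data. These shares therefore do not give the recovery or false calls of the real comparisons.

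Alternatives run were an added value of 0.1, no filter on low values, fits of only the groups compared, the replicate number as a block, each library left out in turn, an adipocyte covariate, a minimum fold change of 1.5, an estimated correlation for the lists, and the alternatives chosen later. Correlations between libraries of a group ran from 0.902 to 0.972 in Sham, 0.868 to 0.968 in AngII and 0.950 to 0.983 in AngII + RvE1. No library was left out of the fit that the report describes.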

Results

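Aortas of mice were profiled by RNA sequencing in 3 groups of 5 libraries. Sham mice formed the control group. AngII mice received angiotensin II, the vasoconstrictor peptide of the renin-angiotensin system, by infusion at 750 ng per kg per minute to raise blood pressure. AngII + RvE1 mice received the same infusion and intraperitoneal injections of resolvin E1 (RvE1), a lipid mediator made from eicosapentaenoic acid that takes part in ending inflammation, at 2 µg per kg per day. The series title names ChemR23, the receptor encoded by Cmklr1, and protection against hypertension and vascular remodeling as its subject. The deposited table gives 1 normalised value per gene and library for 34714 genes, treated here as FPKM. The values of a library summed to between 385846 and 514281, and between 11466 and 12996 genes reached a value of 1. Read depth per library is unknown, so no counting interval can be given. The labels do not say that the libraries came from separate animals, so p-values measure the spread between these samples. Coordinates below are on mm10, from the RefSeq annotation of GRCm38.p6, and cover the whole gene.

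The libraries differed in more than their treatment. The first principal component of the tested genes held 41.1% of the variance and placed AngII libraries 3, 5 and 4 (scores 78.9, 75.8 and 32.9) apart from the other 12, which lay between -28.9 and 2.37. The lymphocyte list mean was 5.17, 4.03 and 5.83 on the log2 scale in AngII libraries 3, 4 and 5, against 1.10 and 0.85 in AngII libraries 1 and 2, and 0.53 to 2.45 in Sham. Genes at a value of 1 or more numbered 12996, 12882 and 12894 in AngII libraries 3, 4 and 5 and at most 12248 elsewhere. Fabp4, a lipid chaperone of fat cells, or the hemoglobin gene Hba-a1 had the highest value in every library. The contractile smooth muscle list mean ranged from 5.67 to 8.07 within Sham alone. Cardiac muscle genes also varied within groups, with a list mean of 0.67 in AngII library 1 and 6.95 in AngII library 2.

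The comparison of AngII with Sham asks which aortic genes differ after angiotensin II infusion. Dbp, a transcription factor of the circadian clock output, had the smallest p-value and rose from 4.11 ± 1.62 to 79.7 ± 30.7 FPKM (SD, n = 5 each), a difference of 3.94 on the log2 scale (SE 0.31, limma adjusted p = 2.26e-05). Some immune genes rose as well, among them the antigen presentation genes Cd74 and Tap1 and 11 of 25 interferon response genes. Of 20 contractile smooth muscle genes 3 fell, and the list test did not pass with an estimated correlation (adjusted p = 0.886). Over all 12603 genes tested, 298 were higher and 102 lower in AngII than in Sham.

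Of the 18 clock genes tested, 8 rose and 4 fell. The counts were 8 and 5 when adjusted over the list alone. Per3 (log2 difference 1.69, adjusted p = 0.000517), Tef (1.39, 0.00126) and Ciart (1.75, 0.00132) rose with Dbp, and so did Nr1d1 (1.65, 0.00480) and Nr1d2 (1.36, 0.00249), which encode the repressors REV-ERB alpha and beta. Arntl, which encodes the core activator BMAL1, fell from 9.02 ± 1.84 to 2.40 ± 1.17 FPKM (log2 difference -1.61, SE 0.22, limma adjusted p = 0.00249). Its partner Npas2 fell from 5.84 ± 2.38 to 0.561 ± 0.222 FPKM (-2.06, SE 0.26, adjusted p = 0.00132), and Nfil3, a repressor that opposes Dbp, fell by 1.97 on the log2 scale (adjusted p = 0.0117). Dbp lies on chromosome 7 from 45705100 to 45710203 and Arntl on chromosome 7 from 113178471 to 113314126. The labels give no time of collection. Members moved both ways, so the list test was not past the threshold (camera adjusted p = 0.0858). With AngII libraries 3, 4 and 5 left out, 8 of the 12 were called in the same direction (6 higher and 2 lower) and 1 other clock gene was called, while Nr1d1 and Nfil3 were not.

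**Figure D1:**
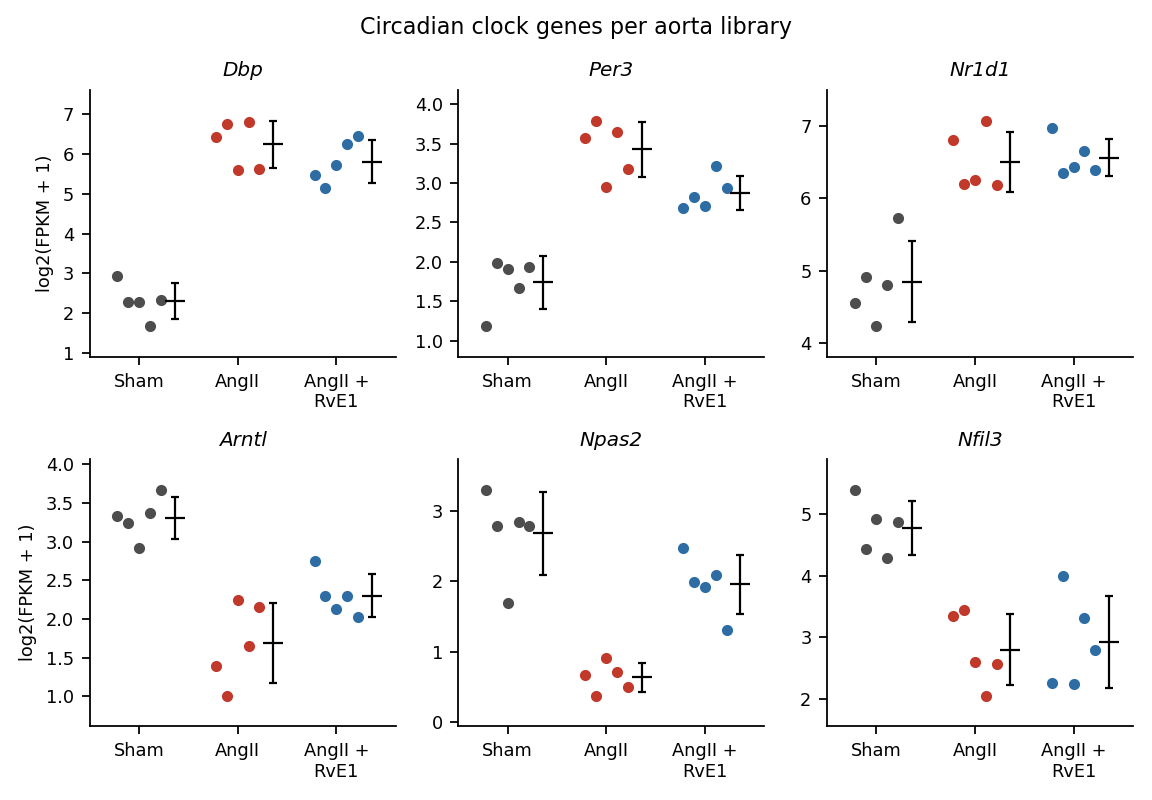
Values of 6 circadian clock genes per library on the log2(FPKM + 1) scale, with 1 point per library and the mean and SD of the 5 libraries beside each group. For Dbp, Per3 and Nr1d1 every AngII library lies above every Sham library, and for Arntl, Npas2 and Nfil3 every AngII library lies below.

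In the interferon response list 11 of 25 members rose and 0 fell, or 23 and 0 when adjusted over the list alone. Gbp3, an interferon-inducible GTPase, rose by 0.96 on the log2 scale (adjusted p = 0.0177), Irf7, a transcription factor of the type I interferon response, by 1.70 (0.0225) and Xaf1 by 0.93 (0.0263). Irf7 was 5.34 ± 2.03 FPKM in Sham and 22.1 ± 13.9 FPKM in AngII. In the macrophage and monocyte list 5 of 23 members rose, or 19 when adjusted over the list alone. They were the complement C1q genes C1qa (1.39, adjusted p = 0.0409), C1qb (1.47, 0.0436) and C1qc (1.42, 0.0384), the scavenger receptor gene Cd163 (0.74, 0.0458), and Lyve1 (1.22, 0.0454), a marker of resident vessel wall macrophages and lymphatic endothelium. Ccl8, a monocyte chemoattractant, rose from 3.51 ± 2.43 to 67.0 ± 64.8 FPKM (log2 difference 3.12, SE 0.76, adjusted p = 0.0403), and Il34, a ligand of the CSF1 receptor, rose by 0.61 (adjusted p = 0.0421). These were the 2 of 25 chemokine and cytokine genes past the threshold. Cd74, the invariant chain of MHC class II, rose from 143 ± 39.1 to 1188 ± 1129 FPKM (2.41, SE 0.61, adjusted p = 0.0465). Tap1, Plac8 and Ucp2, a mitochondrial carrier abundant in leukocytes, rose by 1.86, 2.05 and 1.84 on the log2 scale (adjusted p = 0.0300, 0.0309 and 0.0319). The list tests gave adjusted p = 4.39e-11 for interferon response and 1.34e-07 for macrophages with a preset correlation, and adjusted p = 0.886 for each with an estimated correlation. Lymphocyte genes moved with these lists, since the same 3 AngII libraries held the highest lymphocyte list means. No lymphocyte gene passed the threshold among 15 tested, and their median log2 difference was 1.69. Without AngII libraries 3, 4 and 5, 0 interferon and 0 macrophage genes were called, with medians of 0.47 and 0.47 (median SE 0.25 and 0.26) against 0.90 and 1.33 with all libraries (0.22 and 0.38).

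Of the smooth muscle genes, Kcnmb1, the beta subunit of the vascular BK potassium channel, fell from 27.9 ± 15.9 to 8.07 ± 3.84 FPKM (log2 difference -1.57, SE 0.39, limma adjusted p = 0.0450). Myocd, which encodes the coactivator myocardin, fell by 1.63 on the log2 scale and Itga8, an integrin of smooth muscle, fell by 1.73 (adjusted p = 0.0454 and 0.0458). Adjusted over the list alone, 14 of the 20 members were lower. The median log2 difference of the list was -1.19, with a camera adjusted p = 2.63e-13 at a preset correlation and adjusted p = 0.886 with an estimated correlation. Acta2, smooth muscle actin, was 3179 ± 2165 FPKM in Sham and 934 ± 402 FPKM in AngII (-1.56, adjusted p = 0.0714), and Myh11 was 367 ± 180 and 135 ± 53.9 FPKM (-1.34, adjusted p = 0.0652). Neither passed the threshold. Among 30 vasomotor genes, Gucy1b1, a subunit of the nitric oxide receptor guanylate cyclase, fell by 1.32 (adjusted p = 0.0454). Lmcd1 and Scube3 each fell by 1.98 (adjusted p = 0.0126 and 0.0300), and the matrix gene Ogn by 1.35 (0.0454). Sost, which encodes the Wnt inhibitor sclerostin and lies on chromosome 11 from 101962458 to 101967015, fell from 124 ± 69.2 to 26.3 ± 21.8 FPKM (-2.37, SE 0.55, adjusted p = 0.0348). Without AngII libraries 3, 4 and 5 no smooth muscle gene was called, with a list median of -0.86 (median SE 0.56, against 0.41 with all libraries). With single libraries left out, the number of lower smooth muscle genes ran from 0, as without Sham library 1, to 16 without Sham library 3.

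Cyp2e1, a cytochrome P450 expressed in liver and fat, rose from 193 ± 113 to 1052 ± 309 FPKM (log2 difference 2.58, SE 0.35, limma adjusted p = 0.00249). Cfd, which encodes the adipokine adipsin (complement factor D), rose by 1.54 (adjusted p = 0.0300) and was the 1 of 21 adipocyte genes called. Prdm16, a regulator of brown and beige fat, fell by 0.84 (adjusted p = 0.0263), as the 1 of 14 brown fat genes called. Scd2, a desaturase of lipid synthesis, fell by 1.56 and Slc25a34 by 1.39 (adjusted p = 0.0300 and 0.0263), with Fam13c at -1.36 (0.0146) and Ccdc42 at -1.91 (0.0197). The amino acid transporter gene Slc7a8 and the metallothionein gene Mt3 rose by 1.80 and 1.86 (adjusted p = 0.0223 and 0.0300). Bnip3, Herpud1 and Cd55 rose by 0.91, 0.52 and 1.61 (0.0486, 0.0372 and 0.0491). The adipocyte list mean was 8.29 ± 0.39 in AngII and 8.12 ± 0.49 in Sham (SD, n = 5 each, 2-sided exact permutation p = 0.540).

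The remaining genes chosen in advance did not pass the threshold. The angiotensin receptor gene Agtr1a was 2.18 ± 0.696 FPKM in Sham and 4.37 ± 1.22 FPKM in AngII (log2 difference 0.75, limma adjusted p = 0.0785). Cmklr1, the gene of the RvE1 receptor ChemR23, was 8.68 ± 3.58 and 10.5 ± 3.24 FPKM (0.30, adjusted p = 0.501). The collagen genes Col1a1 and Col3a1 differed by 0.22 and 0.12 (0.805 and 0.882) and Fn1 by -0.35 (0.631). Values for Tgfb1, Vcam1 and Cybb were 1.10, 1.30 and 1.67 (0.0987, 0.0872 and 0.0599), for Nox4 -1.35 (0.0766), for Ccl2 0.51 (0.586) and for Il1b 0.67 (0.365). Ltb4r1, Agtr1b and Il6 were under the filter on low values and were not tested.

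limma's moderated test with Benjamini-Hochberg adjustment gave 400 calls, and 3307 genes had an unadjusted p under 0.05. All libraries of the groups stood apart for 261 of the 400 called genes, and for 3.70% of all tested genes against 0.794% by chance. The median log2 difference of all tested genes was 0.11. Rescaling the libraries by their median ratio lowered it to 0.01 and changed the calls to 253 higher and 241 lower, so the share of higher calls went from 74.5% to 51.2%. Relative to the median of 0.11, the interferon list median of 0.90 and the smooth muscle median of -1.19 kept their directions. The counts rested on single libraries. Leaving out AngII library 1 or 2 gave 1155 or 1378 higher and 171 or 341 lower; leaving out AngII library 3, 4 or 5 gave 90, 54 or 62 higher and 25, 22 or 16 lower. Without Sham library 2 or 5 there were 77 or 68 higher and 23 or 17 lower, without Sham library 3 or 4 there were 555 or 50 lower, and without AngII + RvE1 library 1, 3 or 4 there were 181, 181 or 164 higher and 63, 65 or 56 lower. Fitting AngII and Sham alone gave 30 and 7. Leaving AngII libraries 3, 4 and 5 out, 20 were higher and 2 lower.

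**Figure D2:**
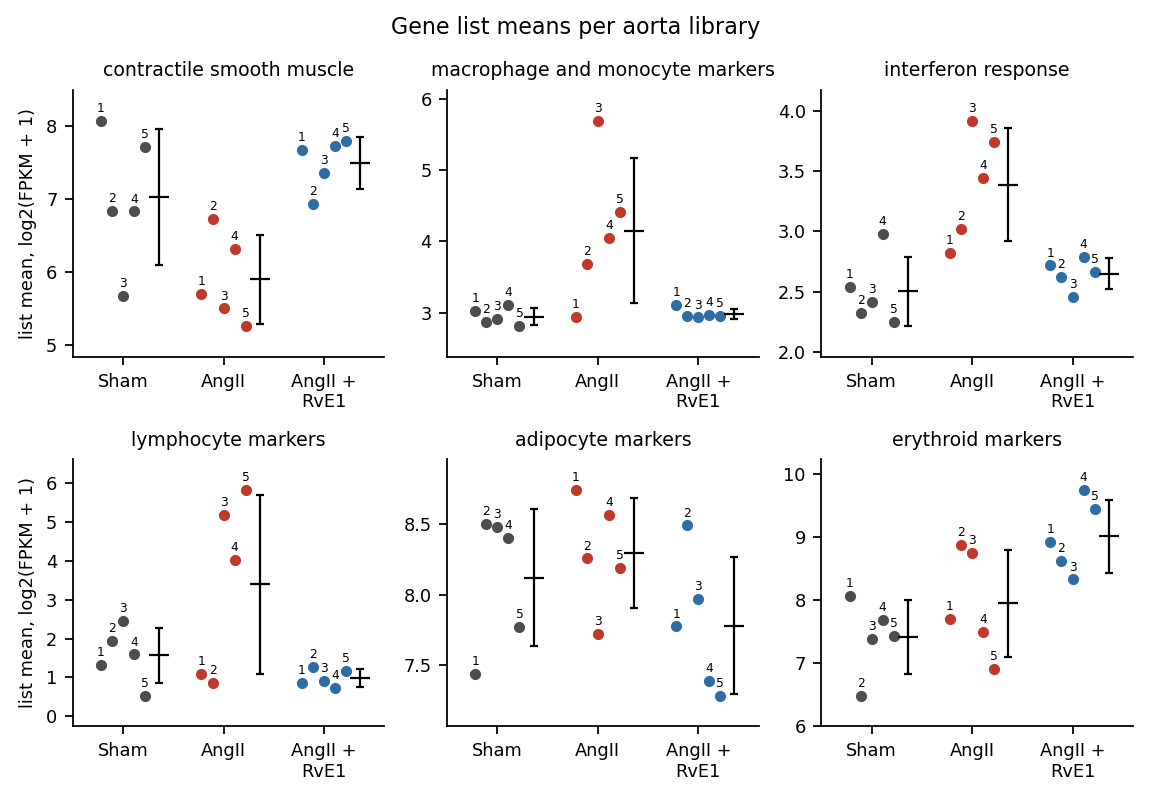
Mean log2(FPKM + 1) of the tested members of 6 gene lists in each library, numbered by replicate, with the mean and SD of the 5 libraries beside each group. Contractile smooth muscle means lie between 6.93 and 7.79 in AngII + RvE1 and between 5.25 and 6.73 in AngII. AngII libraries 3, 4 and 5 hold the highest lymphocyte list means.

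The comparison of AngII + RvE1 with AngII asks what RvE1 changes in infused mice. Of 20 contractile smooth muscle genes 16 rose and 0 fell. Acta2 rose from 934 ± 402 to 3831 ± 811 FPKM (SD, n = 5 each), a log2 difference of 2.11 (SE 0.47, limma adjusted p = 0.0206). Of the immune lists, 10 of 23 macrophage genes, 11 of 25 interferon response genes and 7 of 16 complement genes fell and 0 rose. Cyp2e1 fell from 1052 ± 309 to 191 ± 61.7 FPKM (-2.46, SE 0.35, adjusted p = 0.00953). In all, 531 genes were higher and 543 lower.

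Among smooth muscle genes, Kcnmb1 (log2 difference 2.03, SE 0.39, limma adjusted p = 0.0156), the actin-filament gene Lmod1 (1.81, 0.0171), Cnn1, which encodes calponin (2.21, 0.0175), and Myh11, smooth muscle myosin heavy chain (1.92, 0.0175), had the smallest adjusted p. Kcnmb1 lies on chromosome 11 from 33962955 to 33973641 and Acta2 on chromosome 19 from 34240336 to 34255585. Tagln, Itga8, Smtn and Myocd also rose (1.89, 2.15, 1.72 and 1.42). The list median was 1.66, and the list test gave adjusted p = 7.43e-17 with a preset correlation and adjusted p = 0.886 with an estimated correlation. The list mean was 7.49 ± 0.36 in AngII + RvE1 and 5.90 ± 0.61 in AngII (SD, n = 5 each, 2-sided exact permutation p = 0.00794, the smallest possible, or 0.171 adjusted over 108 tests). Every AngII + RvE1 library lay above every AngII library. Sham libraries spanned 5.67 to 8.07. Of 30 vasomotor genes 9 rose and 1 fell. Rgs4, a regulator of G protein signalling, rose by 1.41, the BK channel gene Kcnma1 by 1.12, and the phosphodiesterase genes Pde3a and Pde5a by 1.20 and 1.29 (adjusted p = 0.0231, 0.0234, 0.0235 and 0.0244). The adipocyte list mean was 7.78 ± 0.49 in AngII + RvE1 and 8.29 ± 0.39 in AngII (exact permutation p = 0.103). Without AngII library 5, AngII + RvE1 library 5, or AngII libraries 3, 4 and 5, 0 of the 20 smooth muscle genes passed the threshold, with list medians of 1.52, 1.57 and 1.39 (median SE 0.44, 0.45 and 0.56, against 0.41 with all libraries); without AngII library 3 the count was 9, and without AngII + RvE1 library 1 or 4 it was 5 or 1.

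In the noncollagen matrix list 7 of 34 genes rose and 0 fell, among them the elastic fiber genes Mfap4 (log2 difference 2.42, limma adjusted p = 0.0227), Fbln5 (1.57, 0.0290), Mfap5 (1.49, 0.0338) and Eln (2.04, 0.0372), and Postn, which encodes periostin (1.65, 0.0340). Col18a1 (2.05, 0.0204), Col15a1 (1.53, 0.0205), Loxl1 (1.49, 0.0323) and P3h2 (1.24, 0.0372) were the 4 of 30 collagen and collagen processing genes called. Col1a1 and Col3a1 differed by 0.64 and 0.45 (adjusted p = 0.398 and 0.534) and Fn1 by 1.33 (0.0600), without passing. In the TGF-beta list 5 of 25 rose and 1 fell. Ltbp1, a latent TGF-beta binding protein, rose by 1.69 (0.0189), Pmepa1 by 1.05 (0.0205), Ltbp3 by 0.92 (0.0227) and Tgfb2 by 1.53 (0.0327), while Tgfbr3 fell by 0.41 (0.0388). Tgfb1 differed by -0.85 (0.154). The list tests gave adjusted p = 2.54e-07 for noncollagen matrix, 4.63e-09 for collagens and 0.000441 for TGF-beta with a preset correlation, and adjusted p = 0.886 for each with an estimated correlation. Sost rose from 26.3 ± 21.8 to 120 ± 34.6 FPKM (2.51, adjusted p = 0.0204). Npnt, Ptprz1, Ccdc42, Scube3 and Optc rose by 2.28, 2.24, 2.25, 2.17 and 2.15. Without AngII libraries 3, 4 and 5, 0 genes of these 3 lists were called, with medians of 0.46 for noncollagen matrix, 0.50 for collagens and 0.50 for TGF-beta (median SE 0.45, 0.45 and 0.30), against 0.87, 0.66 and 0.32 with all libraries (0.36, 0.33 and 0.25).

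In the macrophage list Cd163 fell by 0.999 on the log2 scale (limma adjusted p = 0.0148), Lyve1 by 1.45 (0.0189), Folr2 by 1.02 (0.0301) and the CSF1 receptor gene Csf1r by 1.54 (0.0352). In the interferon list Oas2 fell by 1.23 (0.0237), Ifi44 by 0.83 (0.0261) and Irf7 by 1.39 (0.0293). Complement C3 fell from 207 ± 42.5 to 80.1 ± 29.7 FPKM (-1.41, SE 0.27, adjusted p = 0.0151), with Cfb at -1.59 (0.0280) and Cd55 at -1.72 (0.0266). Of the chemokine and cytokine genes, 6 of 25 fell: Il34 (-0.63), Il33 (-1.22), Ccl8 (-2.71), Ccl5 (-2.98), Cxcl13 (-2.97) and Ccl11 (-0.56). The phagocyte NADPH oxidase gene Cybb fell by 1.69 (0.0400), while Nox4, the isoform of vessel wall cells, rose by 1.55 (0.0379). Cybb was 19.0, 5.29 and 17.8 FPKM in AngII libraries 3, 4 and 5, but 1.38 and 2.68 in AngII libraries 1 and 2. Without Sham library 2 neither Cybb nor Nox4 was called. Cd209b, a lectin of lymphoid and marginal zone macrophages, fell from 79.1 ± 83.6 to 0.874 ± 0.189 FPKM (-3.83, SE 1.02, adjusted p = 0.0364). H2-DMb2, Gimap3, Il2rg and Cd53, all leukocyte genes, fell by 3.10, 3.06, 2.53 and 2.31 (0.0483, 0.0437, 0.0325 and 0.0483). Gimap3 was 57.2, 27.5 and 92.6 FPKM in AngII libraries 3, 4 and 5, but 1.48 and 1.31 in AngII libraries 1 and 2. H2-DMb2 was 83.8, 28.2 and 139 against 1.61 and 1.61. Cd209b, Il2rg, Cd53, Ccl8, Ccl5 and Cxcl13 were likewise far higher in AngII libraries 3, 4 and 5 than in 1 and 2. The list tests gave adjusted p = 3.61e-07 for macrophages, 1.23e-07 for interferon response, 0.00219 for complement and 0.000160 for chemokines, and adjusted p = 0.886 for each with an estimated correlation. The lymphocyte list moved with them, with 2 of 15 members called lower (Nkg7 and Cd37) and a mean of 0.99 ± 0.23 in AngII + RvE1 against 3.40 ± 2.30 in AngII (SD, n = 5 each, exact permutation p = 0.103). Without AngII libraries 3, 4 and 5, 0 macrophage, 0 interferon, 0 complement and 0 chemokine genes were called, with medians of -0.35, -0.29, -0.40 and -0.23 (median SE 0.26, 0.25, 0.37 and 0.31) against -1.12, -0.70, -0.99 and -0.77 with all libraries (0.38, 0.22, 0.35 and 0.38).

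In the adipocyte list 4 of 21 genes fell and 0 rose: the lipid droplet gene Cidec by 0.93 on the log2 scale, Cfd and the adipokine gene Retn each by 1.27, and the lipoprotein lipase gene Lpl by 0.96 (limma adjusted p = 0.0268, 0.0354, 0.0420 and 0.0435). Slc7a10, an amino acid transporter of white fat cells, fell by 2.30 (0.0135), and Prdm16 rose by 1.14 (0.0108). Prdm16 was the 1 of 14 brown fat genes called. The brown fat list mean was 6.28 ± 0.37 in AngII + RvE1 and 6.28 ± 1.13 in AngII (exact permutation p = 0.992). The adipocyte list test gave adjusted p = 0.0141 with a preset correlation and adjusted p = 0.894 with an estimated correlation. In the list of resolvin and eicosanoid genes, Lgr6, a receptor for maresin 1, rose by 1.98 (0.0148), and Ptgis, the prostacyclin synthase, rose by 2.03 (0.0245), while Ltc4s, the leukotriene C4 synthase, fell by 0.88 (0.0325). These were the 3 of 19 members called. The list median was -0.29 and its test pointed up (camera adjusted p = 0.788). Cmklr1 was 10.5 ± 3.24 FPKM in AngII and 7.41 ± 1.06 FPKM in AngII + RvE1 (-0.41, adjusted p = 0.319). Among clock genes Npas2 rose by 1.33 (0.0159), and Ciart and Cry1 fell by 1.16 and 0.65 (0.0148 and 0.0278). Of 15 clock genes with a known phase, 13 differed opposite to AngII against Sham, a comparison that shares the AngII libraries. Angiotensinogen (Agt) fell by 1.56 (0.0489), while Agtr1a differed by -0.24 (0.533). Agt was 14.0, 8.80 and 7.38 FPKM in AngII libraries 3, 4 and 5, but 1.34 and 1.72 in AngII libraries 1 and 2. In AngII + RvE1 libraries it lay between 0.54 and 1.67 FPKM. Without Sham library 2 it was not called. Vcam1, Ccl2 and Il1b differed by -0.93, -0.79 and -0.69 (0.165, 0.351 and 0.331). The endothelial genes Mmrn1 and Kdr fell by 1.66 and 0.60 (0.0177 and 0.0291), and Adam12 and Ctss among the proteases fell by 1.47 and 2.47 (0.0135 and 0.0331) while Serpine2 rose by 1.60 (0.0265). Ctss was 282, 50.2 and 145 FPKM in AngII libraries 3, 4 and 5, and 10.1 and 22.2 in AngII libraries 1 and 2.

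limma gave 1074 calls, and 3652 genes had an unadjusted p under 0.05. For 781 of the called genes, and 11.1% of all tested genes against 0.794% by chance, the libraries of the groups did not overlap. The median log2 difference of all tested genes was -0.11, and -0.04 after rescaling by the median ratio, with 766 higher and 505 lower calls (60.3% higher, against 49.4%). Leaving out AngII library 3, 4 or 5 gave 240, 303 or 44 higher and 151, 179 or 54 lower, and leaving out AngII library 1 or 2 gave 1173 or 1314 lower. Without AngII + RvE1 library 1, 3, 4 or 5 there were 84, 292, 70 or 52 higher and 82, 172, 66 or 53 lower, without Sham library 2 there were 329 lower and without Sham library 3 there were 831 higher. Without AngII libraries 3, 4 and 5 the counts were 0 and 6. With the smooth muscle or the lymphocyte list mean as a covariate, 1 and 5 genes were called.

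The comparison of AngII + RvE1 with Sham asks what differs when both are given. Limma called 3 genes, and 843 had an unadjusted p under 0.05. All 3 belong to the clock. Dbp rose from 4.11 ± 1.62 to 58.1 ± 21.9 FPKM (SD, n = 5 each), a log2 difference of 3.51 (SE 0.31, limma adjusted p = 0.000112). Nr1d1 rose from 29.7 ± 13.3 to 94.3 ± 18.0 FPKM (1.71, SE 0.25, adjusted p = 0.0365), and Cry1, a repressor of the clock, fell from 4.39 ± 0.657 to 1.62 ± 0.462 FPKM (-1.05, SE 0.16, adjusted p = 0.0365). In all 3 genes no AngII + RvE1 library overlapped a Sham library. Nr1d1 lies on chromosome 11 from 98767932 to 98775377 and Cry1 on chromosome 10 from 85131700 to 85185054. Adjusted over the list alone, 8 of the 18 clock genes were higher and 5 lower. The clock genes Per3 (1.13, adjusted p = 0.0741), Nr1d2 (1.08, 0.0881), Tef (0.97, 0.0881) and Nfil3 (-1.85, 0.114) did not pass over all genes, nor did Bpgm (1.15, 0.343), which red blood cells express.

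No smooth muscle, macrophage or interferon gene was called between AngII + RvE1 and Sham. The median log2 differences were 0.50 for smooth muscle, -0.06 for macrophages and 0.22 for interferon response. The erythroid list moved up without a call over all genes: 7 of 7 members were higher when adjusted over the list alone, with a list mean of 9.01 ± 0.58 in AngII + RvE1, 7.94 ± 0.85 in AngII and 7.41 ± 0.58 in Sham. Its list test gave adjusted p = 7.02e-12 with a preset correlation and adjusted p = 0.886 with an estimated correlation. Hemoglobin genes took 5.93% to 17.8% of the summed values in AngII + RvE1 libraries and 1.30% to 4.61% in Sham libraries. Leaving out single libraries changed the counts to between 1 and 4 higher and between 0 and 4 lower. Dbp stayed called each time. Nr1d1 was not called without Sham library 1, 2, 3 or 4, AngII library 2, or AngII + RvE1 library 1, 3, 4 or 5 (adjusted p from 0.0531 to 0.147), nor was Cry1 without Sham library 2, 3, 4 or 5, AngII library 2 or 4, or AngII + RvE1 library 1, 3, 4 or 5 (adjusted p from 0.0531 to 0.178).

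Among genes called in both of the first comparisons, 253 moved in opposite directions: 176 were higher in AngII than in Sham and lower in AngII + RvE1 than in AngII, and 77 the reverse. Ccl8 (log2 differences 3.12 and -2.71), Cyp2e1 (2.58 and -2.46), Cd74 (2.41 and -2.35) and the MHC class II genes H2-Ab1 (2.20 and -2.20) and H2-Eb1 (2.16 and -2.09) had the largest changes among those that rose and then fell. Sost (-2.37 and 2.51), Scube3 (-1.98 and 2.17) and Lmcd1 (-1.98 and 2.03) led those that fell and then rose. Independent lists of these sizes would share 12.8 and 4.30 genes. Both comparisons use the same AngII libraries, so chance alone gives opposite differences. In 100 simulated sets with no effect the median was 0 opposite calls, the highest 527, and 7 sets gave at least 253. The correlation of log2 differences across genes was -0.83 against a simulated median of -0.67, and 6 sets were as low. Genes are not independent replicates. The covariance was -0.21 against a simulated mean of -0.05 (lowest of 100 sets -0.15). With the AngII libraries split between the comparisons in 20 ways, the correlation ran from -0.79 to -0.23 and the opposite calls from 0 to 112, with a median of 0. Without AngII libraries 3, 4 and 5, 6 opposite calls were made, and without AngII library 5 there were 31.

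**Figure D3:**
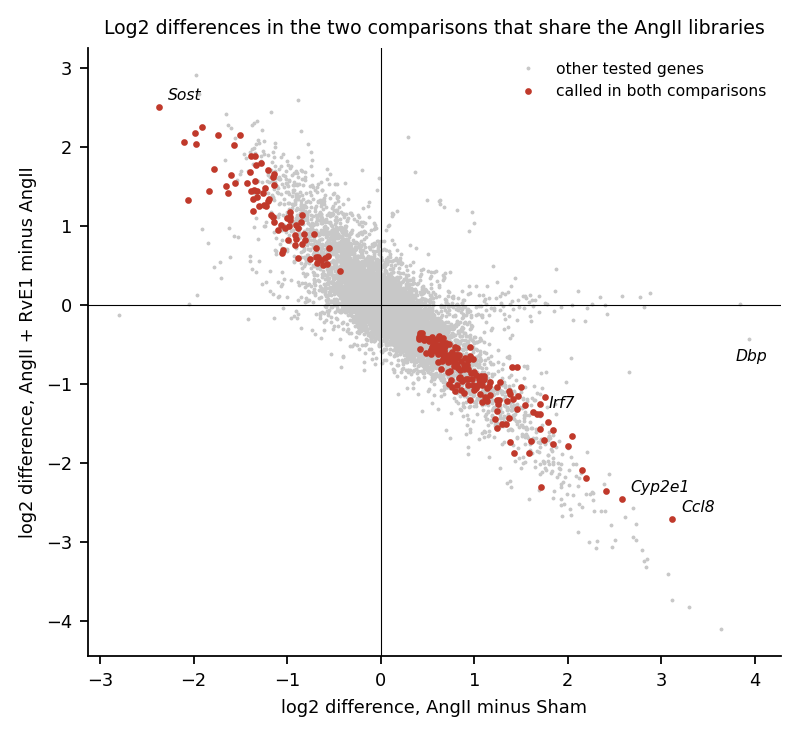
Log2 differences of each of the 12603 tested genes, AngII minus Sham on the horizontal axis and AngII + RvE1 minus AngII on the vertical axis; colored points are genes called in both comparisons. The points follow a falling diagonal (correlation -0.83 across genes), part of which comes from the shared AngII libraries, and Dbp lies off it at 3.94 and -0.43.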

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

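A library was flagged when its gap to the nearest of the other 4 in its group exceeded 0.71 of the group's range. Chance flags about 1 in 20 groups. Of 108 groups of list means 7 were flagged, and of 360 groups of values of named genes 20. Of 9 groups of library sums, detected genes and hemoglobin shares 0 were flagged. The number of flags is therefore near the number that chance gives. The rule scales a gap to the range of its group, so this number does not weigh how large a gap is on the log2 scale.

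The flagged list means, on the log2 scale, were macrophage and monocyte markers in AngII + RvE1 library 1 (3.10, others 2.93 to 2.97), neutrophil markers in Sham library 4 (3.03, others 0.88 to 1.22), skeletal muscle markers in AngII library 4 (7.64, others 1.19 to 2.37), skeletal muscle markers in AngII + RvE1 library 2 (4.36, others 1.80 to 2.18), Schwann and neuronal markers in Sham library 4 (3.27, others 1.48 to 1.96), Schwann and neuronal markers in AngII + RvE1 library 5 (1.97, others 3.28 to 3.81) and immediate early genes in AngII library 4 (3.70, others 4.32 to 4.49). Among these list means, skeletal muscle genes in AngII library 4 and in AngII + RvE1 library 2 had the largest gaps on the log2 scale. As a share of the group's range, neutrophil markers in Sham library 4 (0.840) passed skeletal muscle in AngII library 4 (0.817).

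The flagged genes, on the log2 scale, were Plac8 in Sham library 5 (1.42, others 2.41 to 2.66), Prdm16 in Sham library 3 (2.30, others 2.87 to 3.08), Herpud1 in AngII library 3 (5.66, others 5.94 to 6.01), Herpud1 in AngII + RvE1 library 5 (5.34, others 5.56 to 5.65), Cd55 in AngII + RvE1 library 5 (1.53, others 2.15 to 2.38), Cmklr1 in AngII + RvE1 library 3 (2.72, others 3.07 to 3.21), Ccl2 in Sham library 4 (2.90, others 1.14 to 1.58), Ccl2 in AngII library 3 (4.65, others 1.22 to 2.03) and Npnt in AngII + RvE1 library 2 (6.14, others 6.86 to 7.08). Further flags were Gimap3 in Sham library 3 (2.78, others 0.89 to 1.41), Cd53 in Sham library 3 (3.18, others 1.39 to 1.83), Fbln5 in AngII library 2 (6.30, others 4.38 to 4.93), Postn in AngII + RvE1 library 2 (7.49, others 8.51 to 8.83), Adam12 in Sham library 1 (1.24, others 2.25 to 2.48), Ctss in AngII + RvE1 library 5 (3.51, others 3.23 to 3.31), Ltbp1 in AngII + RvE1 library 2 (4.96, others 5.69 to 5.98), Mcm7 in Sham library 3 (2.44, others 2.78 to 2.85), Rgs4 in AngII + RvE1 library 5 (5.56, others 4.78 to 4.85), Lpl in Sham library 1 (7.29, others 8.41 to 8.77) and H2-Ab1 in AngII + RvE1 library 5 (6.69, others 5.44 to 5.76).

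Immune genes higher in AngII than in Sham. All tests here were chosen after seeing the result, and the limits of both were changed after their outcomes were known, the second so that exclusion also needs a gene still called; its earlier limit of 2 SE alone would have excluded lymphoid tissue as the whole cause. Lymphoid tissue collected with some aortas is a technical explanation. Of 20 genes of a separate lymph node list, 18 had their 3 highest values in AngII libraries 3, 4 and 5. Of the 8 that pass the filter 6 did, against 14.98% of all tested genes. These libraries were the 3 with the highest lymphocyte list means, and the lymph node list includes lymphocyte genes. The count, taken over mixed cell types, therefore fits lymphoid tissue but cannot tell it from lymphocytes of another source. Of the list's members, Glycam1 was 55.4, 35.0 and 85.5 FPKM in AngII libraries 3, 4 and 5. Marco was 287, 61.5 and 148 FPKM there, and at most 2.67 in the rest. In Sham library 3, of the control group, Glycam1 was 13.6 and Ltb 9.78 FPKM. In all other libraries Glycam1 was at most 0.14. These genes were picked after their values were seen, and which cells carried them was not tested. Over all 48 tested interferon and macrophage genes the lymphocyte covariate took the median log2 difference from 0.94 (SE 0.30) to 0.62 (SE 0.27), with 47 of 48 above 0 and 0 called since the differences shrank more than their SE, so lymphoid tissue as the whole cause and an effect of the infusion beside it cannot be told apart. By list the medians went from 0.90 to 0.57 (interferon, SE 0.23) and from 1.33 to 0.70 (macrophage, SE 0.34), and for AngII + RvE1 against AngII from -0.70 to -0.33 (SE 0.25) and from -1.12 to -0.42 (SE 0.37), with 0 called; lymphocytes recruited by the infusion could raise the same markers.

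Smooth muscle genes higher in AngII + RvE1 than in AngII. Both tests were chosen after seeing list means, and the limit of the second was tightened after its value was known. Dilution by lymphoid RNA alone would lower the other cell types alike. Smooth muscle less the mean of adipocyte, endothelial and fibroblast lists differed by 1.87 on the log2 scale (exact permutation p = 0.00794). Between AngII and Sham the same measure differed by -1.31 (exact p = 0.0238). These values speak against an even dilution only. The endothelial list mean was 4.62 in AngII and 4.18 in AngII + RvE1, so lymphoid tissue that brings such cells along is not excluded. AngII libraries 1 and 2, with low lymphocyte list means (1.10 and 0.85), had -0.47 and 0.44 on the smooth muscle measure. Both lay below every AngII + RvE1 library (lowest 0.88). Sham libraries 3 and 4 also lay below, at -0.12 and 0.58, so these AngII libraries do not settle it. For a different share of vessel wall and fat, the adipocyte covariate left 0.760 of the median log2 difference (1.66 to 1.26, SE 0.41, 11 genes called), so a change within the cells and a changed share of wall and fat cannot be told apart; the adipocyte list mean itself ranged only from 7.28 to 8.74 over the libraries. With the lymphocyte covariate the list median went from 1.66 (SE 0.41) to 1.08 (SE 0.46) and 0 genes were called, as the difference shrank and its SE grew.

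Clock genes between AngII and Sham. Both tests were chosen after seeing the result. Composition as followed by the adipocyte, smooth muscle and lymphocyte list means did not remove the clock calls. The fewest clock genes called in any of 4 covariate fits was 9, all among the 12 called without a covariate. Other cell types were not tried as covariates. Schwann and neuronal markers had means of 1.95 in Sham, 3.35 in AngII and 3.21 in AngII + RvE1. Other changes of composition are therefore not excluded. All 15 members with a known phase differed in the direction of 1 phase shift, as a different clock phase at collection would give. A different time of day at collection and a shift made by the infusion could each give this. The group labels hold no collection times to separate them. Between AngII + RvE1 and Sham, 14 of the 15 differed in the same direction, though that comparison shares the Sham libraries. Between AngII + RvE1 and AngII, 13 of 15 differed in reverse, though that comparison shares the AngII libraries.

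The splits were planned before the result. Of 100 divisions of the 10 libraries of a comparison in 5 and 5, those that called as many genes as the real groups numbered 4 for AngII against Sham (real 400, highest other 1773), 1 for AngII + RvE1 against AngII (real 1074, highest other 5) and 2 for AngII + RvE1 against Sham (real 3, highest other 830); the real division is among those counted. The division with 1773 calls set Sham libraries 1 and 5 and AngII libraries 3, 4 and 5 against the rest. In both comparisons with Sham, at least 1 division that mixes the groups thus gave more calls than the treatment did. For AngII + RvE1 against AngII no other division fitted gave more.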

How the results depend on the processing

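Of the 12 clock calls between AngII and Sham, 10 to 12 were called in the same direction with any library left out, 9 to 12 with each covariate fit and 8 with AngII libraries 3, 4 and 5 left out. Most other calls of the first 2 comparisons did not hold without AngII libraries 3, 4 and 5 or with the smooth muscle or lymphocyte covariate. These covariates differ between the groups, so they also remove differences that a treatment makes. Depth per library is unknown, so how far it limits low genes cannot be given. Alternatives for counts only (edgeR with other size factors, DESeq2, limma-voom, filters on counts and CPM) were not run, since the file holds no counts. Where the sentences that follow give no cause, the cause was not tested.

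Counts are given as AngII against Sham higher and lower, AngII + RvE1 against AngII higher and lower, AngII + RvE1 against Sham higher and lower, and opposite calls; those of the report were 298, 102, 531, 543, 2, 1 and 253. An added value of 0.1 gave 320, 114, 520, 550, 2, 1 and 270, and a fold change of at least 1.5 gave 257, 92, 493, 415, 2, 1 and 201. With no filter on low values the counts were 122, 29, 213, 192, 1, 0 and 87. With only the 2 groups compared they were 30, 7, 851, 489, 1, 0 and 26. The adipocyte covariate gave 1268, 482, 436, 1118, 1, 0 and 998. Of the alternatives chosen after seeing the data, median-ratio rescaling gave 253, 241, 766, 505, 2, 1 and 330; the smooth muscle covariate 53, 41, 0, 1, 1, 0 and 1; the lymphocyte covariate 45, 12, 0, 5, 5, 1 and 5; both of these covariates 184, 78, 0, 1, 5, 2 and 1; AngII libraries 3, 4 and 5 left out 20, 2, 0, 6, 4, 1 and 6, with fewer samples; and array weights 2104, 717, 1502, 2967, 13, 4 and 1991. Leaving out each library in turn gave 54 to 1378, 16 to 555, 44 to 831, 53 to 1314, 1 to 4, 0 to 4 and 31 to 1145. Of the list tests 48 were past the threshold with a preset correlation, 0 with the estimated correlation and 38 to 52 with a library left out.

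With the replicate number as a block the counts were 72, 37, 269, 164, 1, 0 and 69. The labels do not say that the numbers pair, 4 of 15 same-number pairs had a correlation over 0.1 (range -0.41 to 0.52), and in 2 pairs the first library correlated best with the library of its own number, so the numbers were not used as a design.

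The log2 differences of genes named by the rule that turned direction follow. None of them was called in the direction it turned to, and the cause was not tested. Genes that the rule does not name were not checked for turns. With the adipocyte covariate they were Agtr1a 0.0264, Col3a1 -0.17 (AngII + RvE1 against AngII), and Tgfb1 -0.0563, Vcam1 -0.00213, Nox4 -0.00948 (AngII + RvE1 against Sham). With the smooth muscle covariate they were Fn1 0.51 (AngII against Sham), and P3h2 -0.00742, Nox4 -0.0273, Col1a1 -0.67, Col3a1 -0.73, Il1b 0.0340 (AngII + RvE1 against AngII), and Il1b 0.20, Nox4 -0.27, Cybb 0.20 (AngII + RvE1 against Sham). With the lymphocyte covariate they were Ccl2 -0.0549 (AngII against Sham), and Tgfb1 0.000690, Il1b 0.16 (AngII + RvE1 against AngII), and Il1b 0.19, Nox4 -0.00336, Cybb 0.28 (AngII + RvE1 against Sham). With the smooth muscle and lymphocyte covariates they were Fn1 0.45, Ccl2 -0.00594, Il1b -0.0252 (AngII against Sham), and P3h2 -0.0117, Nox4 -0.12, Col1a1 -0.65, Col3a1 -0.68, Il1b 0.24 (AngII + RvE1 against AngII), and Il1b 0.22, Nox4 -0.27, Cybb 0.23 (AngII + RvE1 against Sham). With AngII libraries 3, 4 and 5 left out they were Cmklr1 -0.0381, Ccl2 -0.25, Il1b -0.0558 (AngII against Sham), and Tgfb1 0.14, Il1b 0.0411, Vcam1 0.0219 (AngII + RvE1 against AngII). With array weights they were Col1a1 -0.39, Col3a1 -0.45, Ccl2 -0.23, Il1b -0.0555 (AngII against Sham), and Ccl2 0.0239 (AngII + RvE1 against AngII). With each library left out in turn, the genes that turned ranged as Ccl2 -0.52 to 0.00603, Cmklr1 -0.37 to 0.0285, Cybb -0.0778 to 0.0261, Il1b -0.16 to 0.13, Nox4 -0.15 to 0.48 (AngII + RvE1 against Sham), and Ccl2 -0.0897 to 0.80, Col1a1 -0.15 to 0.48, Col3a1 -0.17 to 0.35 (AngII against Sham).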

Other observations

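Markers of Schwann cells and neurons had a mean of 1.95 in Sham, 3.35 in AngII and 3.21 in AngII + RvE1 libraries on the log2 scale. Mesothelial and epithelial markers reached 3.10, 3.73 and 3.27 in Sham libraries 1, 2 and 4 and 0.76 and 0.88 in Sham libraries 3 and 5. Cardiac muscle markers were 6.95 in AngII library 2 and 5.05 in AngII library 4, and 0.67, 0.74 and 0.96 in AngII libraries 1, 3 and 5. Cell cycle genes had list means of 3.63, 2.43 and 3.44 in AngII libraries 3, 4 and 5, and at most 1.96 in every other library.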
